A study of Homo sapiens with 161 samples.

How the data were processed

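Colorectal cancer cells were profiled by RNA sequencing of tumorspheres and xenograft tumours, and by chromatin immunoprecipitation sequencing (ChIP-seq) of p53. The lines were DLD1, HCT116, HCT8 and SW620. Per the labels, RNA libraries were made with a stranded total RNA kit for picogram inputs and ChIP libraries with an enzymatic DNA kit, reads were aligned with STAR to hg38 (GRCh38), and featureCounts assigned them to genes or repeat elements. The versions of STAR, featureCounts and the gene annotation, and the strand setting used in counting, are not given in the sources used here. The deposited values are raw counts per gene or per repeat element, without normalization by the authors. In the files every value was a whole number, and each table held gene rows with a symbol, a type and a chromosome together with repeat rows with a class. There were 60719 genes for RNA and 58780 genes for ChIP, and each table held 16108 repeat elements. Start and end positions are not in the count tables, so genes are identified by symbol and, at first mention of the main ones, by Ensembl identifier.

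Groups were taken from the labels. The tumorspheres had 32 groups of line, sphere state, day and treatment, with 3 libraries each except the SW620 established day 7 DMSO group with 2. The label term for the sphere state other than established is written as "new". Each combination of sphere state and day was sequenced as a pool of its own, so drug contrasts were taken within pools, while contrasts between days or sphere states cannot be told apart from the pool. For the established day 1 pool the sample titles say day 7 while the time label and the column names say day 1, and day 1 was used. In the xenografts 1 library was left out of all groups because its title and its cell line label name different lines. The series description gives other library numbers for the 3 assays than the tables used here, and the tables were followed. The label "AZA" is not expanded in the sources and was used as given.

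Genes with low counts were removed with filterByExpr of edgeR (minimum count 10, minimum total 15), and libraries were scaled by trimmed mean of M-values (TMM) over genes and repeats together. Negative binomial quasi-likelihood models (glmQLFit with robust estimation, glmQLFTest; edgeR 4.0.16, R 4.3.3) were fitted with 1 coefficient per group: per line for the drug effect in tumorspheres, over DMSO tumorspheres for day and sphere state, per line for xenografts, over both xenograft lines for differences between them, and over all ChIP libraries. P values were adjusted by Benjamini-Hochberg over genes and repeats together, with a threshold of 0.05, and called genes and repeats were counted apart. All tests were two-sided. Errors (±) of log2 fold changes are standard errors, taken as the log2 fold change over the square root of its F statistic, and those of levels are SD. DESeq2 1.42.0 was run as a second tool. In the drug effect of a line, the contrast was the mean over the 4 conditions of sphere state and day, and a joint F test asked whether the effect differed between conditions. No drug contrast was paired: replicate letters were tested as a block because residual correlations between same-letter libraries were above 0.1 in every pair of only 3 of the conditions.

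The test on gene lists was camera of limma 3.58.1 on log2 CPM, the counts scaled to library size, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted within a contrast. There were 24 gene lists and 8 repeat families, introduced where their results are given. Counts of members past the threshold are given over all genes tested and adjusted over the list alone. The comparisons, lists, rule for naming genes and most alternatives were fixed before the data were examined. The rule named, for each line mean, xenograft contrast against PBS and ChIP contrast, up to 8 protein-coding genes with the largest rise and up to 8 with the largest fall. These had to pass the threshold, have a mean log2 CPM of 2 or more and, for line means, keep 1 sign in the 4 conditions. It also named up to 4 members of each list with the smallest p, up to 5 repeats per direction, and CDKN1A and MDM2 everywhere. Lists in the contrasts of day and sphere state were added after seeing the data. Some planned results are not reported here.

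The alternatives were DESeq2, DESeq2's size factors in edgeR, no filter, a replicate block, library-size scaling for ChIP, and leaving out each replicate. Added after seeing the data were fits without libraries with a TMM factor under 0.7, without 1 HCT8 library, without the established day 1 condition, and with sample weights (limma voomLmFit). Regroupings of the same libraries were drawn for contrasts of at least 3 libraries per arm. Changes planted in simulated counts were used to test the procedure. They were planted in features with a mean log2 CPM of 2 or more. The counts were drawn independently, without outlying libraries or shared structure, so recovery in the real libraries may be lower. In the tumorsphere designs with 11 or more libraries per arm it recovered at least 76.1% of the planted 1.5-fold changes. In the single condition simulated, established day 7, added after seeing the data, it recovered 16.4% in DLD1, 28.4% in HCT116 and HCT8 and 25.4% in SW620, and 64.2% to 85.1% of the planted 2-fold changes, so 0 calls there do not exclude small changes. In the xenograft designs of 3TC against PBS it recovered 9% in HCT116 and 16.4% in SW620, and 64.2% and 58.2% of the planted 2-fold changes. Depth ranged from 4.66 to 15.74 M counts (M for mega) per tumorsphere library, 1.63 to 5.08 M per xenograft library and 12.27 to 22.02 M per ChIP library. Reads were not traced to molecules, so the replicate spread, not the counts alone, sets the precision. Permutation tests used 1e+05 permutations. Figures were drawn with python 3.11.15 and matplotlib 3.10.9.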

Results

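Gene and repeat counts were measured in 95 tumorsphere libraries, 50 xenograft libraries and 16 ChIP libraries. Tumorspheres are balls of cancer cells grown in suspension without serum, a culture that favours cells with stem-like properties. They were treated with 3TC (lamivudine, an inhibitor of reverse transcriptases, including those of LINE-1 elements) at 1 to 10 micromolar, or with the solvent DMSO. Spheres of DLD1, HCT116, HCT8 and SW620 were sampled on day 1 and day 7, in new and in established spheres, with 3 libraries per group and 2 in the SW620 established day 7 DMSO group. Xenografts were tumours of HCT116 or SW620 cells in nude mice. The tools and genome builds given name no step that separates mouse reads, so xenograft values may include reads of mouse cells. Mice received PBS, 3TC (50 mg per kg, 3 times per week, 20 days), the agent labelled AZA, or 3TC with AZA. HCT116 tumours numbered 4 for PBS, 7 for 3TC, 5 for AZA and 6 for 3TC with AZA, and SW620 tumours numbered 6, 7, 5 and 9 in that order. ChIP compared p53 immunoprecipitates (IP) with input DNA, 2 libraries each per line. The titles of the HCT116 and HCT8 ChIP libraries carry DMSO, while those of DLD1 and SW620 name no treatment.

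Tumorsphere libraries held 4.66 to 15.74 M counts (M for mega; median 7.22), of which 13.64% to 64.65% lay on repeats. Xenograft libraries were shallower, at 1.63 to 5.08 M (median 3.48), with 9.1% to 83.41% on repeats. ChIP libraries held 12.27 to 22.02 M, with 90.39% to 91.98% on repeats. The libraries with a scaling factor under 0.7 were DLD1 new day 7 DMSO replicate C (0.518, with 64.65% of counts on repeats), HCT116 PBS tumour 3 (0.196, with 75.89% of counts on small structured RNAs), and SW620 PBS tumour 5, SW620 3TC tumour 7, SW620 AZA tumour 1, SW620 3TC with AZA tumour 9 and HCT116 AZA tumour 2, each with over 70% of counts on repeats.

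Levels in the untreated lines are given without a test. CDKN1A, which encodes the p21 inhibitor of the cell cycle and is a p53 target, stood in DMSO spheres at a mean log2 CPM of 7.51 ± 0.38 (SD, n = 12) in HCT116 and 6.61 ± 0.92 in HCT8. It stood at 4.87 ± 0.51 in DLD1 (n = 12) and 0.48 ± 1.33 in SW620 (n = 11). The p53 target list averaged 4.32 ± 0.20 in HCT116, 4.11 ± 0.16 in HCT8, 3.33 ± 0.21 in DLD1 and 2.82 ± 0.13 in SW620. MDM2, the p53 target that marks p53 for degradation, ranged from 5.96 ± 0.37 in SW620 to 7.21 ± 0.24 in HCT116. Interferon-stimulated genes were highest in HCT116 (4.20 ± 0.74) and lowest in SW620 (0.81 ± 0.17), and colon differentiation genes were highest in HCT8 (2.59 ± 0.55) and lowest in HCT116 (-2.30 ± 0.30). WNT and intestinal stem cell genes ran from 1.33 ± 0.15 in HCT116 to 4.83 ± 0.31 in SW620, and mesenchymal genes from 0.61 in HCT8 to 2.44 in SW620. Young L1 elements stood between 12.50 ± 0.88 and 12.84 ± 0.53 in the 4 lines, while HERV-H ranged from 9.15 ± 0.91 in HCT8 to 11.49 ± 0.38 in HCT116. In PBS xenografts CDKN1A stood at 4.93 ± 1.15 in HCT116 (n = 4) and 1.94 ± 1.13 in SW620 (n = 6). These levels were not tested, since libraries of 1 line are not independent samples of a kind of line.

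The drug effect in spheres was asked of each line as the mean over its 4 conditions, 12 libraries of 3TC against 12 of DMSO (11 of DMSO in SW620). Single replication genes rose with 3TC in each line and single mitotic genes fell in DLD1, HCT116 and HCT8, while every call of the G1/S and G2/M lists as groups was lost with an estimated correlation. RRM2, the ribonucleotide reductase subunit that makes deoxynucleotides for DNA synthesis, rose in all 4 lines (ENSG00000171848.16; log2 0.39 ± 0.08 in DLD1, 0.42 ± 0.09 in HCT116, 0.42 ± 0.07 in HCT8 and 0.64 ± 0.08 in SW620). FANCI, a DNA crosslink repair protein, rose in DLD1, HCT116 and HCT8, by 0.27 ± 0.05, 0.31 ± 0.07 and 0.34 ± 0.07. CCNB1, the cyclin that drives entry into mitosis, fell by 0.58 ± 0.10, 0.57 ± 0.10 and 0.62 ± 0.09 in the same lines, and KIF20A, a motor of cytokinesis, fell by 0.67 ± 0.09, 0.60 ± 0.12 and 0.57 ± 0.12. Of 224 genes called in any line, 197 were called in 1 line, 22 in 2, 4 in 3 and 1 in 4. The direction differed in 1 shared gene, the scaffold protein AKAP12, which rose in DLD1 (0.44 ± 0.08) and fell in HCT116 (-0.36 ± 0.07).

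**Figure D1:**
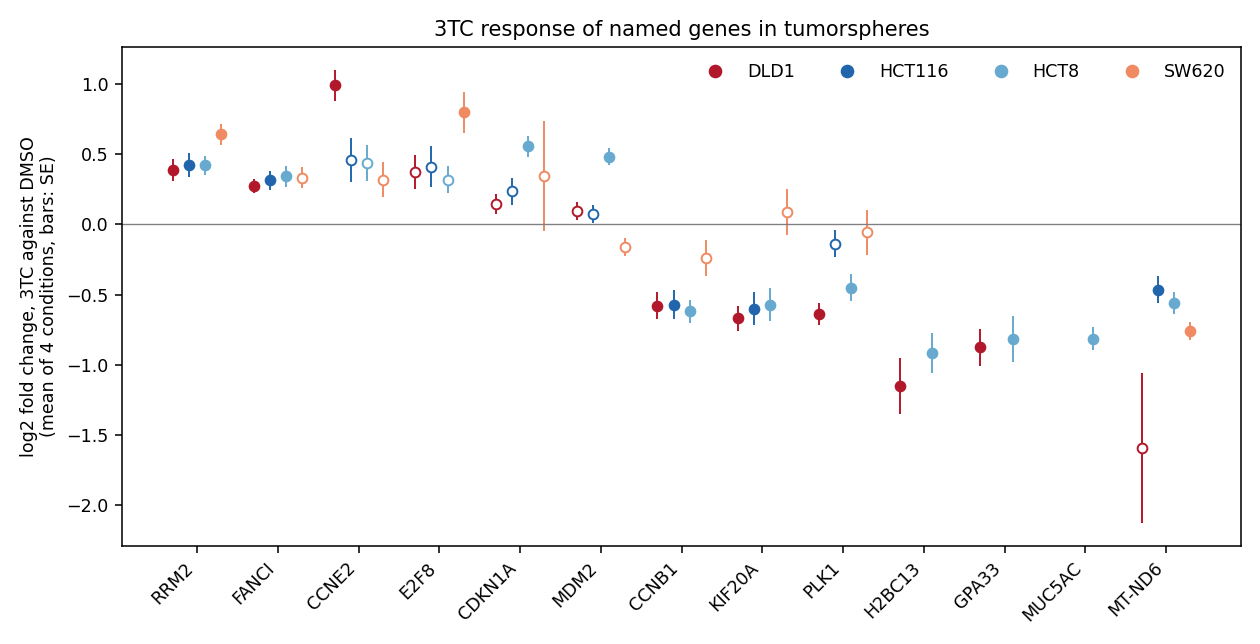
The log2 fold change of 3TC against DMSO (y axis, mean of 4 conditions) is plotted for 13 genes in 4 lines; bars are standard errors, filled points passed an adjusted p of 0.05, open points did not, and a missing point means that the gene was below the count filter in that line. RRM2 lies above 0 with a filled point in every line, and CCNB1 and KIF20A lie below 0 with filled points in DLD1, HCT116 and HCT8.

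In DLD1, where 80 genes passed (20 up, 60 down, of 16049 tested), the largest rise was that of CCNE2, a cyclin that starts S phase (ENSG00000175305.17; 0.99 ± 0.11, adjusted p = 4.1e-05). DTL, which removes replication licensing factors in S phase, rose by 0.48 ± 0.08, and the repair factors ATAD5 and BRIP1 rose by 0.39 ± 0.09 and 0.35 ± 0.08. MYBL1, SCML1 and SLC25A29 rose by 0.66 ± 0.15, 0.51 ± 0.11 and 0.41 ± 0.09. PLK1, a kinase of mitosis, fell by 0.64 ± 0.08 (adjusted p = 2.3e-04) and CDC20, an activator of the anaphase-promoting complex, by 0.51 ± 0.09. The largest falls included the histone genes H2BC13 at -1.15 ± 0.20, H2BC14 at -1.03 ± 0.23, H1-3 at -0.70 ± 0.13 and H1-5 at -0.66 ± 0.13. Other falls were those of the surface antigen GPA33 (-0.88 ± 0.13), the adhesion molecules CEACAM6 (-0.94 ± 0.21) and CEACAM5 (-0.49 ± 0.11), and the microvillus protein VIL1 (-0.43 ± 0.10). CRTAM fell by 0.76 ± 0.16, MYC by 0.28 ± 0.06 and the endoplasmic reticulum chaperone CALR by 0.37 ± 0.07. The p53 targets CDKN1A (0.14 ± 0.07, adjusted p = 0.470) and MDM2 (0.10 ± 0.06) did not pass. DESeq2 called 190 genes, and without replicate A, B or C of every group edgeR called 6, 1 and 17, and with a replicate block 25; without DLD1 new day 7 DMSO replicate C alone it called 152.

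In HCT116, 16 genes passed (4 up, 12 down, of 16089). Besides RRM2 and FANCI, FAM111A, a protease that acts at replication forks, rose by 0.46 ± 0.10 (adjusted p = 0.041). The falls included the signalling genes RGS2 (-0.46 ± 0.08), EREG (-0.44), DKK1 (-0.39 ± 0.08), S100A6 (-0.38) and ANXA3 (-0.37 ± 0.06). MT-ND6, the only protein-coding gene on the light strand of the mitochondrial genome, fell by 0.47 ± 0.10. CDKN1A was 0.23 ± 0.09 (adjusted p = 0.402) and MDM2 0.08. DESeq2 called 100 genes, and edgeR with a replicate block 4. Without replicate A, B or C of every group edgeR called 0 each time, so no single HCT116 call outlasted the loss of 8 of the 24 libraries.

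HCT8 had the most calls, 45 up and 86 down of 16312, with several p53 targets among the rises. CDKN1A rose by 0.56 ± 0.07 (ENSG00000124762.14; adjusted p = 2.7e-05) and MDM2 by 0.48 ± 0.06 (adjusted p = 1.2e-05). These are means over unlike conditions. New day 7 alone gave 2625 calls, against 1 on new day 1, 0 on established day 1 and 2 on established day 7. The CDKN1A rise lay in new spheres, as given below. The p53 targets POLH, a polymerase that copies past lesions, DDB2, a sensor of damaged DNA, and GDF15, a secreted stress factor, rose by 0.52 ± 0.08, 0.53 ± 0.09 and 0.41 ± 0.08. The S-phase genes DUT, BRCA2, PCNA and TYMS rose by 0.46 ± 0.10, 0.43 ± 0.09, 0.34 ± 0.08 and 0.34 ± 0.08; KIF27, BCL2L15, FAM217B and MYO5A rose by 0.55 ± 0.13, 0.49, 0.46 and 0.44. The histone genes H2BC14 (-2.17 ± 0.44), H2BC13 (-0.92 ± 0.14) and H1-3 (-0.68 ± 0.12) fell, as did the mitotic genes PLK1 (-0.45 ± 0.10) and BUB1 (-0.40 ± 0.08). Other falls were the mucins MUC5AC (-0.81 ± 0.08, adjusted p = 3.4e-07) and MUC2 (-0.57 ± 0.10), the fatty acid carrier FABP1 (-0.86 ± 0.16), GPA33 (-0.82 ± 0.16), the intestinal transcription factor CDX1 (-0.70 ± 0.11) and DMKN (-0.86 ± 0.19). MT-ND6 fell by 0.56 ± 0.08 (adjusted p = 3.9e-05). DESeq2 called 266 genes, and without replicate A, B or C edgeR called 47, 33 and 57; leaving out the established day 1 condition gave 418.

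SW620 showed 30 calls (20 up, 10 down, of 17179). Rises included the E2F family member E2F8 (0.80 ± 0.14, adjusted p = 0.0055), the histone chaperone ASF1B (0.78 ± 0.11), the kinase PKMYT1 (0.67 ± 0.10), the transcription factor MYBL2 (0.55 ± 0.09), the nuclease EXO1 (0.53 ± 0.11) and the helicase factor CDC45 (0.49 ± 0.09). PCYOX1L, TCF19 and SHCBP1 rose by 0.60 ± 0.11, 0.59 ± 0.11 and 0.59 ± 0.13. MT-ND6 fell most, by 0.76 ± 0.07 (adjusted p = 4.2e-09), followed by the transcription factor MKX (-0.68 ± 0.10) and the matrix genes COL8A1 (-0.63 ± 0.14) and TNC (-0.39 ± 0.08). AJUBA, F5, ANXA3 and TRIB1 fell by 0.40 ± 0.07, 0.37 ± 0.07, 0.35 ± 0.08 and 0.35 ± 0.08. CDKN1A was 0.34 ± 0.39 and MDM2 -0.16 ± 0.06 (adjusted p = 0.42). DESeq2 called 103 genes, and edgeR with a replicate block 89. Without replicate B of every group edgeR called 4. Without replicate A or C the established day 7 DMSO group keeps 1 library, so those counts enter only the ranges given below and are not read as results. In every line the MT-ND6 values come from libraries that differ by pool in the ratio of MT-ND6 to MT-ND5: it was higher by a mean log2 of 4.28 in the established day 1 pool than in the established day 7 pool. The new pools differed too: in SW620 DMSO spheres the log2 ratio was -3.792 on new day 1 and -4.186 on new day 7, against -5.673 on established day 7. Whether strand-related counting also differed between 3TC and DMSO libraries was not tested, so the MT-ND6 falls may not be an effect of 3TC.

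The fixed lists were tested as groups. The DNA repair list had 18 measured members and rose in DLD1 with 2 members past the threshold over all genes and 10 adjusted over the list alone (median 0.22; adjusted p = 6.6e-12, and adjusted p = 0.016 with an estimated correlation). In the other lines its call was lost with an estimated correlation: HCT116 (1 member, 6 adjusted over the list alone, median 0.20; adjusted p = 0.18 with an estimated correlation), HCT8 (2 and 10, median 0.22; adjusted p = 0.10 with an estimated correlation) and SW620 (1 and 11, median 0.27; adjusted p = 0.11 with an estimated correlation). The list of 19 G1/S genes had medians of 0.13, 0.18, 0.11 and 0.17 in DLD1, HCT116, HCT8 and SW620, with 2, 1, 3 and 3 members past the threshold and 6 adjusted over the list alone in each line. In HCT116 all 19 of 19 were positive. Its calls were lost with an estimated correlation (adjusted p = 0.20, 0.18, 0.77 and 0.28 with an estimated correlation). The 20 G2/M genes went down in DLD1 (4 members, 11 adjusted over the list alone, median -0.21), HCT116 (2 and 4, median -0.13) and HCT8 (6 and 9, median -0.24). These calls too were lost (adjusted p = 0.14, 0.30 and 0.22 with an estimated correlation), and in SW620 the list was not called (adjusted p = 0.81).

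Among the p53 targets, 9 of 29 passed in HCT8, all up, with 14 adjusted over the list alone (median 0.24; adjusted p = 2.4e-16, and adjusted p = 0.00104 with an estimated correlation). The list was not tested in single conditions, so this result does not show a rise in established HCT8 spheres. In HCT116 no single target passed in edgeR, 6 did adjusted over the list alone, and the list rose (median 0.17; adjusted p = 6.7e-08, and adjusted p = 0.032 with an estimated correlation); DDB2 stood at 0.34 (adjusted p = 0.15) there. In DLD1 none of 28 passed, and the list call (median 0.04, adjusted p = 0.029) was lost, with adjusted p = 0.42 with an estimated correlation. In SW620 the list was not called (adjusted p = 0.56).

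Colon differentiation genes fell in DLD1 (3 of 12 past the threshold, 9 adjusted over the list alone, median -0.47; adjusted p = 0.022 with an estimated correlation). In HCT8 they had a median of -0.21 (4 of 15, 7 adjusted over the list alone; adjusted p = 0.067 with an estimated correlation), and in SW620 a median of 0.28 (0 of 7 in edgeR, 1 adjusted over the list alone; adjusted p = 0.017, and adjusted p = 0.11 with an estimated correlation). In SW620 antigen presentation genes rose, with 14 of 14 positive and 4 adjusted over the list alone (median 0.15; adjusted p = 0.029 with an estimated correlation). The HLA class I genes HLA-C and HLA-B stood at 0.23 ± 0.06 (adjusted p = 0.16) and 0.30 (adjusted p = 0.22). Interferon-stimulated genes rose in SW620 (median 0.15; adjusted p = 0.0033, and adjusted p = 0.039 with an estimated correlation), where 1 of 22, the sensor of double-stranded RNA OAS3, passed (adjusted p = 0.025). In HCT116 they had a median of 0.09, with 5 adjusted over the list alone and IRF9 at 0.64 (adjusted p = 0.13), and the call was lost (adjusted p = 0.30 with an estimated correlation).

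Mitochondrially encoded genes had medians of -0.18 in DLD1, -0.28 in HCT116 and -0.12 in SW620, with MT-ND6 past the threshold in HCT116, SW620 and HCT8, where the list was not called, and 9 of 13 adjusted over the list alone in HCT116. Each call was lost (adjusted p = 0.55, 0.36 and 0.68 with an estimated correlation). Integrated stress response genes were negative in 13 of 13 in SW620 (median -0.26), PSAT1 among them at -0.51 ± 0.13 (adjusted p = 0.157), and the list call was lost (adjusted p = 0.28 with an estimated correlation). Further calls lost in the same way were the retroelement restriction and nucleic acid sensing genes, up in HCT116 (adjusted p = 0.083 with an estimated correlation), and hypoxia genes, down in HCT116 (adjusted p = 0.61 with an estimated correlation). In DLD1, heat shock genes and small structured RNAs were down (adjusted p = 0.63 with an estimated correlation for both). Of the gene lists tested, 8 of 23 were called in DLD1, 8 of 23 in HCT116, 5 of 24 in HCT8 and 7 of 23 in SW620; 2, 1, 1 and 2 held with an estimated correlation.

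**Figure D2:**
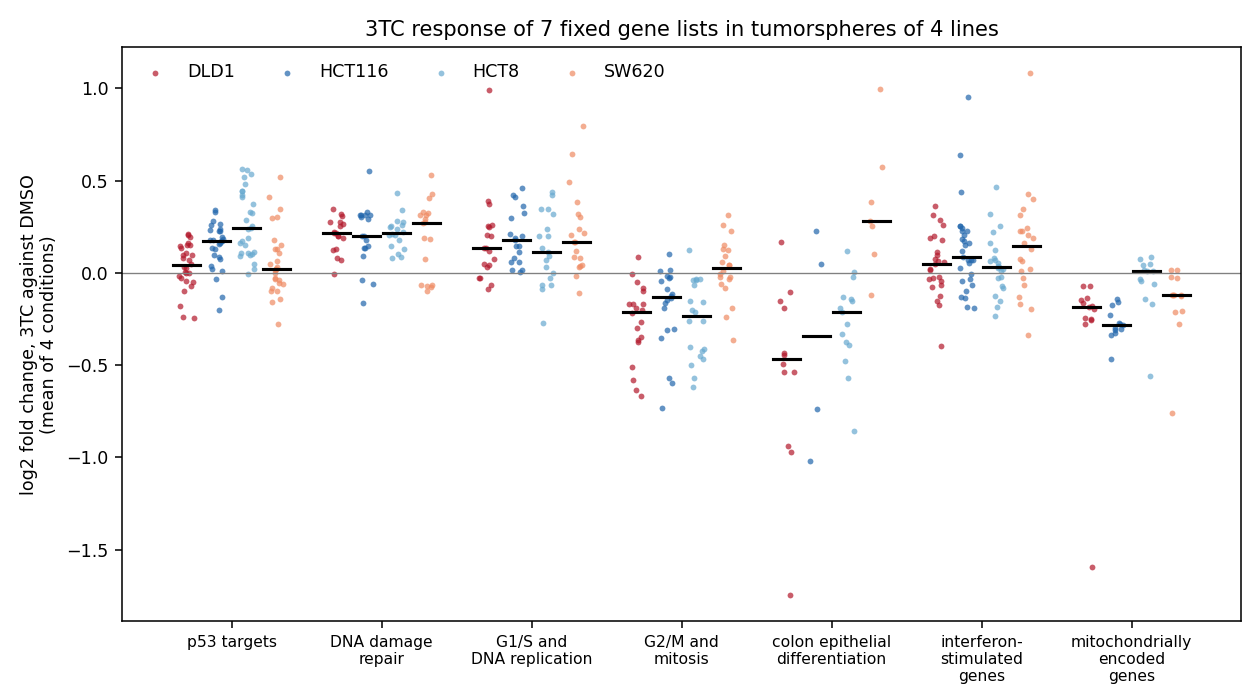
Each point is 1 gene's log2 fold change of 3TC against DMSO (y axis, mean of 4 conditions) in 1 line, grouped by 7 of the fixed lists (x axis); black bars are list medians. The p53 target medians are 0.04 in DLD1, 0.17 in HCT116, 0.24 in HCT8 and 0.02 in SW620, and the DNA repair medians lie above 0 in all 4 lines.

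Among the repeat families, young L1 elements were not called in any line (medians -0.41 in DLD1, -0.05 in HCT116, -0.04 in HCT8 and -0.07 in SW620; adjusted p = 0.34, 0.41, 0.70 and 0.25). That DLD1 median includes new day 7 DMSO replicate C, with 64.65% of counts on repeats. Single repeats past the threshold numbered 1 up and 2 down in DLD1, 1 down in HCT116 (LTR7Y, -0.32 ± 0.07), 4 up and 3 down in HCT8 and 3 up in SW620. In DLD1 other LTR elements (median -0.35), satellites (-0.92), other LINE elements (-0.27) and Alu (-0.23) were called down, and each call was lost (adjusted p = 0.82, 0.75, 0.85 and 0.82 with an estimated correlation). Those DLD1 values moved to medians of 0.04, 0.04, 0.07 and 0.03 without new day 7 DMSO replicate C, the library with 64.65% of counts on repeats. In HCT8 other LINE, other LTR and HERV-K elements were called up (medians 0.10, 0.10 and 0.13; adjusted p = 0.84, 0.77 and 0.77 with an estimated correlation) and Alu down (median -0.09; adjusted p = 0.84 with an estimated correlation). In SW620 other LINE, HERV-H and other LTR elements were called down (medians -0.08, -0.16 and -0.05; adjusted p = 0.73, 0.49 and 0.88 with an estimated correlation). In HCT116 SVA elements were called up (median 0.12) and satellites down (-0.18), with adjusted p = 0.50 and 0.61 with an estimated correlation.

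Single conditions, 3 libraries against 3, asked in which spheres the response was called. New day 7 gave the most calls in DLD1, HCT116 and HCT8, with 2625 genes in HCT8 (1272 up, 1353 down). In that HCT8 contrast the scaling factors were 0.746 to 0.868 in the DMSO libraries and 0.892 to 1.044 in the 3TC libraries, and mitochondrial shares 0.67% to 1.16% and 0.9% to 1.59%, so library composition moved with the treatment. The genes named in single conditions, other than CDKN1A and MDM2, were chosen after their values were seen. There CDKN1A rose by 1.6 ± 0.15 (adjusted p = 1.12e-09), MDM2 by 1.45 ± 0.13 (adjusted p = 2.63e-10), RRM2B, a p53-induced ribonucleotide reductase subunit, by 1.49 ± 0.17 and POLH by 1.26. HYOU1, a chaperone of the endoplasmic reticulum, fell by 1.44 ± 0.12 and PHGDH, the entry enzyme of serine synthesis, by 1.36. The other HCT8 conditions gave 1 call on new day 1 (H2BC14, -2.30 ± 0.40), 2 on established day 7 (MUC5AC, -1.05 ± 0.17, and CEACAM5, -0.84 ± 0.15) and 0 on established day 1 in edgeR (534 at an unadjusted p under 0.05, 1 in DESeq2). Without replicate B or C new day 1 gave 0, and without replicate A, B or C established day 7 gave 1, 0 and 0. In the joint test of whether the effect differed between conditions, HCT8 had 568 genes. CDKN1A went from 0.49 on new day 1 and 1.6 on new day 7 to 0.07 and 0.06 in established spheres. Without replicate A, B or C, HCT8 new day 7 gave 1465, 716 and 1962 calls and the joint test 98, 138 and 138; without new day 7 DMSO replicate B alone, the library with the lowest scaling factor of its group, they gave 1430 and 281.

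In DLD1, 92 genes passed on new day 7 (16 up, 76 down). Falls there included single genes of the endoplasmic reticulum, for which no list was tested in this condition: CRELD2 by 1.44 ± 0.15 (adjusted p = 1.65e-05), PDIA4 by 1.03 ± 0.12, HYOU1 by 1.0, CALR by 1.02 and HSPA5 by 0.90. The epithelial genes GPA33 and CFTR fell by 1.43 and 1.04 and the transcription factor MYB by 1.23. On new day 1, 6 genes passed: CCNE2 (1.69 ± 0.21) and FAM111B (0.91 ± 0.13) rose, and KIF20A (-1.12 ± 0.16), CDC20 (-0.90), PLK1 (-0.88) and NCAPD2 (-0.56 ± 0.10) fell. Established spheres gave 0 calls in edgeR and 0 in DESeq2 on both days, with 420 and 511 genes at an unadjusted p under 0.05 on day 1 and day 7; with a replicate block established day 7 also gave 0. The joint test found 3 genes, MYB, PDIA4 and CRELD2 (DESeq2 34); without replicate A, B or C it found 0. Without replicate A, B or C, new day 1 gave 0, 2 and 2 calls and new day 7 gave 1, 1 and 53; without DMSO replicate C alone new day 7 gave 239.

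In HCT116, 71 genes passed on new day 7 (15 up, 56 down), with rises of DDB2 (1.04 ± 0.18), BTBD19 (1.37) and ARRDC4 (1.74) and falls of S100A6 (-0.97), EREG (-1.11), MT-CYB (-1.10), MT-CO2 (-1.10) and MT-ND3 (-1.28). A replicate block gave 45 calls, and without replicate A, B or C there were 5, 3 and 0. On new day 1, 5 genes passed: E2F7 (0.88 ± 0.16) and the recombination factor RAD54L (0.93 ± 0.18) rose, while MT-ND6 (-1.24 ± 0.20), KIF20A (-1.12) and PLK1 (-0.87) fell; without replicate B or C there were 0. Established spheres gave 0 in edgeR and 0 in DESeq2 on both days (282 and 295 at an unadjusted p under 0.05), and without replicate A established day 7 gave 1. The joint test found only MT-ND6 (adjusted p = 0.022; DESeq2 21), and without replicate A, B or C it found 0. The ratio of MT-ND6 to MT-ND5 differed between the pools that this test compares. A difference in counting therefore cannot be told apart from a different effect of 3TC on MT-ND6. In SW620, 16 genes passed on new day 7, 15 of them up, among them RRM2 (1.13 ± 0.17), the repair genes BRCA1 (1.10 ± 0.17) and BRCA2 (1.11), NUF2 (1.48), which attaches chromosomes to the spindle, and TOP2A (0.77). On new day 1, 4 passed: MT-ND6 (-1.65 ± 0.13), MT-TP (-1.31 ± 0.17) and MT-TQ (-1.72 ± 0.30) fell and AP2A1 (0.63 ± 0.12) rose. On established day 1, 40 passed, with rises of the aldehyde dehydrogenases ALDH1A3 (1.73 ± 0.27) and ALDH3A1 (1.84) and the intestinal transcription factor CDX2 (1.78 ± 0.32), and falls of the stress factor ATF3 (-1.74 ± 0.28) and RASSF6 (-0.98 ± 0.13). A replicate block gave 240 there. Established day 7 gave 0 in edgeR (546 at an unadjusted p under 0.05, 1 in DESeq2). The joint test found 13 genes in SW620, led by MT-ND6 and including NUF2, ASPM, CENPF and TOP2A of mitosis. The MT-ND6 call has the same limit as in HCT116. Without replicate A, B or C the SW620 counts were 2, 2 and 239 on new day 1, 4, 0 and 123 on new day 7 and 0, 0 and 401 on established day 1. Without replicate B the joint test gave 0. Without replicate A or C the established day 7 DMSO group keeps 1 library. Those counts for established day 7 and the joint test therefore enter only the ranges given below and are not read as results.

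Culture time was read from DMSO spheres, as new day 7 minus new day 1 over the 4 lines (12 libraries each). Spheres on day 7 had less RNA of proliferation genes, with 7516 of 19918 genes called (2707 up, 4809 down; DESeq2 8190, with 4212 up and 3978 down; 4240 with a replicate block). All 20 G2/M genes fell (median -2.10; adjusted p = 8.9e-04 with an estimated correlation), among them MKI67, the proliferation marker (-1.95 ± 0.10), and CCNB1 (-2.26 ± 0.10). All 19 G1/S genes fell (median -1.60; adjusted p = 0.0038 with an estimated correlation), with MCM2, a subunit of the replicative helicase, at -1.29 ± 0.10 and RRM2 at -2.58 ± 0.09. All 17 cholesterol synthesis genes fell (median -1.44; adjusted p = 0.0038 with an estimated correlation), with HMGCS1 at -2.01 ± 0.10. Of 18 DNA repair genes 16 fell and 1 rose (median -1.38; adjusted p = 0.0095 with an estimated correlation), the damage kinase ATM being the 1 that rose, by 0.56 ± 0.09. MDM2 fell by 0.68 ± 0.08 and CDKN1A did not pass (-0.17 ± 0.17). All 8 repeat families were called up, from a median of 0.44 in HERV-K to 1.03 in young L1 and 1.98 in satellites, and every such call was lost (adjusted p = 0.42 to 0.55 with an estimated correlation). Without DLD1 new day 7 DMSO replicate C these medians were 0.24, 0.67 and 0.79. The examples in the day and sphere state contrasts, other than MDM2 and CDKN1A, were chosen after values were seen.

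Established day 7 spheres were set against new day 7 spheres in the same fit (11 and 12 libraries). There 10351 genes were called (6522 up, 3829 down; DESeq2 11221, with 5561 up and 5660 down), so in both this and the day contrast the balance of rises and falls differed between the tools. No list in this contrast held, with adjusted p = 0.24 to 0.42 with an estimated correlation for those called with the preset one. Of 13 mitochondrial genes 12 rose and 1 fell (median 1.93): MT-CO1 rose by 2.19 ± 0.12 and MT-ND1 by 1.86 ± 0.11, and MT-ND6 fell by 1.35 ± 0.39. LDHA, the lactate enzyme of glycolysis, fell by 0.83 ± 0.10. CDKN1A fell by 0.93 ± 0.21 and MDM2 did not pass (0.05 ± 0.08). All 8 repeat families were called down, from a median of -0.96 in HERV-K to -2.01 in Alu (-0.81 and -1.85 without DLD1 new day 7 DMSO replicate C), hypoxia genes down (13 of 17, median -1.33) and G1/S genes up (18 of 19, median 0.86). Day and sphere state were each sequenced as separate pools, so neither can be told apart from the pool. DESeq2's scaling moved the median of all genes by 0.10 in the day contrast and by -0.14 in the state contrast, and changes were read relative to that.

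In the xenografts, which asked whether the treatments alter tumours of each line, no gene passed in edgeR in any of the 10 contrasts within a line. For 3TC, AZA and 3TC with AZA against PBS, HCT116 (12532 genes) had 648, 678 and 643 genes at an unadjusted p under 0.05 and DESeq2 called 76, 0 and 1; SW620 (12733 genes) had 477, 189 and 216, with 0 in DESeq2. For 3TC with AZA against 3TC and against AZA, HCT116 had 420 and 200 and SW620 418 and 137 at an unadjusted p under 0.05, with 0 in DESeq2. In HCT116 CDKN1A was 0.18, 0.28 and 0.39 for 3TC, AZA and 3TC with AZA, and MDM2 was 0.31, 0.28 and 0.32. In SW620 CDKN1A was -0.57, -0.30 and -0.78 and MDM2 0.06, 0.09 and 0.02, with adjusted p between 0.837 and 1 in both lines, and the p53 target list was not called in any of these contrasts. In HCT116 with 3TC, VIM, the intermediate filament of mesenchymal cells, stood at -4.15 ± 0.83 (adjusted p = 0.203), ZEB2 at -4.15 and FN1 at -2.75. These falls rested on PBS tumour 3, the library with a scaling factor of 0.196: without it they were -0.66 ± 0.41, -0.40 and -0.07 (adjusted p = 1 for each) and 0 genes passed in edgeR. Without HCT116 PBS tumour 1, 2 or 4, which leaves tumour 3 more weight, that contrast called 16, 19 and 19 genes.

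Gene lists in the xenografts were called with the preset correlation only. Whether reads of mouse host cells entered these lists was not tested. Fibroblast markers were lower in HCT116 with 3TC (median -1.94, 0 of 7 in edgeR, 4 adjusted over the list alone; adjusted p = 0.75 with an estimated correlation), a median that was -0.66 without the low-factor libraries. Mesenchymal genes (median -0.43; adjusted p = 0.75 with an estimated correlation) went the same way and G2/M genes the other (median 0.18; adjusted p = 0.99 with an estimated correlation). In SW620 fibroblast markers, with 8 of 8 negative, had medians of -1.0, -1.35 and -1.08 with 3TC, AZA and both (adjusted p = 0.781, 0.705 and 0.742 with an estimated correlation). Mitochondrial genes were up with 3TC in SW620 (median 0.50; adjusted p = 0.78 with an estimated correlation) and hypoxia genes up with AZA (median 0.19; adjusted p = 0.89 with an estimated correlation). Interferon-stimulated genes were called up in HCT116 with 3TC and AZA (median 0.22; adjusted p = 0.91 with an estimated correlation), a median of 0.04 without the low-factor libraries. All 8 repeat families were called up in HCT116 with AZA, among them other LTR (median 1.29), other LINE (1.15), Alu (1.12) and young L1 (1.37), and all were lost (adjusted p = 0.82 with an estimated correlation). Without AZA tumour 2 (81.31% of counts on repeats) and PBS tumour 3 these medians were 0.48, 0.22, 0.80 and 0.78. In SW620 other LTR was called down in the 3 treatments (medians -0.79, -0.45 and -0.50; adjusted p = 0.78, 0.94 and 0.74 with an estimated correlation). These contrasts share the PBS tumours, and without the low-factor libraries, PBS tumour 5 (83.41% of counts on repeats) among them, the medians were -0.41, -0.30 and -0.26.

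**Figure D3:**
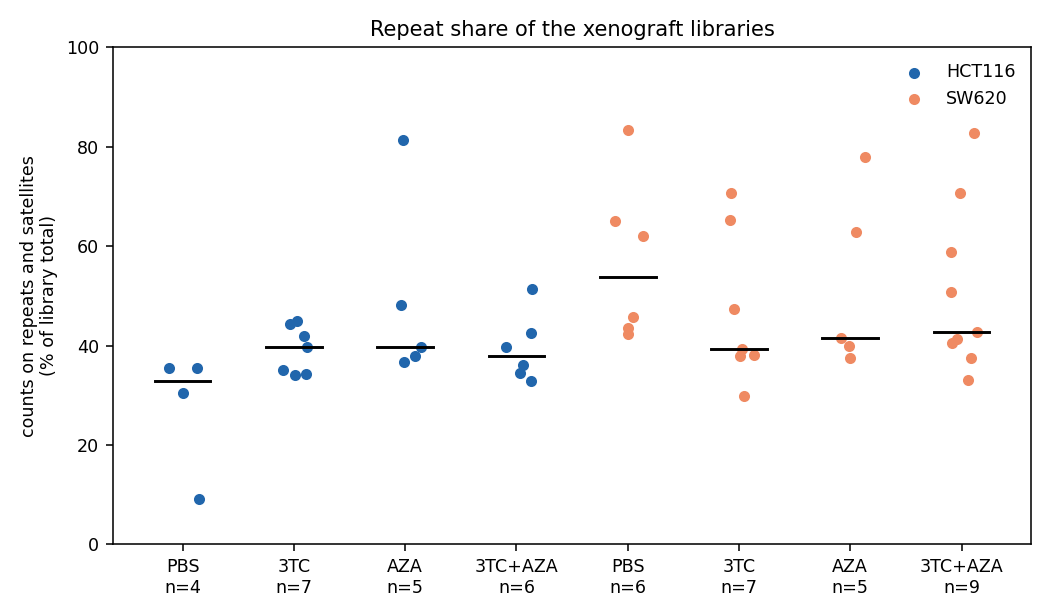
Each point is the share of 1 xenograft library's counts that lay on repeats and satellites (y axis, %), by line and treatment (x axis, with n); black bars are group medians. Shares run from 9.1% to 83.41%, with wide spread inside groups such as the SW620 PBS tumours (42.31% to 83.41%).

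Whether the 3TC effect differed between the tumour lines was tested in both lines together. There 24 of 14782 genes passed, all lower in HCT116 (777 at an unadjusted p under 0.05, DESeq2 50), among them genes of skeletal muscle fibres. ACTA1, actin of muscle fibres, stood at -13.54 ± 2.35 (adjusted p = 0.00412), the myosin MYH4 at -13.93 ± 2.46, creatine kinase CKM at -13.15, the calcium sensor TNNC2 at -12.73 and the giant protein TTN at -12.36. VIM (-4.12 ± 0.81) and the signal recognition particle RNA RN7SL1 (-4.11 ± 0.84) passed as well. These genes were chosen after their values were seen, and whether their reads came from mouse host cells was not tested. HCT116 PBS tumour 3, with ACTA1 at 195.76 CPM and 75.89% of counts on structured RNAs, was needed for the result: without it 0 genes passed in edgeR. SW620 3TC tumour 5, with ACTA1 at 1076.17 CPM, acted in the same direction, and the count was 5 without it. It was 40 without HCT116 3TC tumour 2, and 58, 57 and 52 without HCT116 PBS tumour 1, 2 and 4. The list of erythroid, muscle and fat cell markers, of which only the muscle genes ACTA1, MYH1, MYH2 and CKM were measured, was called up with 3TC in SW620 (median 6.25; adjusted p = 0.78 with an estimated correlation), with a median of 1.16 without 3TC tumour 5, which was left out after its value was seen. For AZA, 0 genes passed in edgeR (828 at an unadjusted p under 0.05, DESeq2 0) and for 3TC with AZA 0 (668, DESeq2 2; 1 in edgeR without HCT116 PBS tumour 1).

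The ChIP asked what p53 antibody DO7 enriches over input in each line. CDKN1A did not pass in DLD1 (0.27 ± 0.30), HCT8 (0.45 ± 0.24) or SW620 (0.47 ± 0.34). In HCT116 the p53 targets CDKN1A (1.5 ± 0.21, adjusted p = 2.4e-11) and AEN, an apoptosis nuclease (1.15 ± 0.19, adjusted p = 1.1e-07), rose, and SPATA18 by 0.55, while FDXR fell by 0.90 (n = 2 against 2, as in every line). MDM2 was -0.22 in DLD1, -0.03 in HCT116, -0.53 ± 0.13 in HCT8 (adjusted p = 9.4e-04) and -0.11 in SW620. In HCT8 GADD45A fell by 2.14 and in DLD1 DDB2 fell by 1.10. The p53 target list as a whole was not called in any line. Counts were taken over whole genes or repeat elements, so a narrow binding site can be missed. A gene that did not rise is therefore not shown to lack p53. The libraries include no control IP, so p53 binding cannot be told apart from other differences between IP and input.

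Counts called in IP against input were 1725 in DLD1 (837 up, 888 down), 3473 in HCT116 (1741 up, 1732 down), 2833 in HCT8 (1274 up, 1559 down) and 661 in SW620 (251 up, 410 down), of 35435 genes. The 8 replicate pairs differed by a chi-square per degree of freedom of 1.052 to 1.278, against a median of 8.544 in spheres. They thus varied little beyond counting noise, and whether they came from separate cultures is not known here. The ChIP p values and counts may therefore not measure the spread between cultures. Among the large rises were those of the axon guidance receptor DCC (0.85 ± 0.11) and CDH12 (0.92 ± 0.16) in DLD1, THSD7B (1.15 ± 0.14) and PTPRD (1.02) in HCT116, ROBO2 (0.96 ± 0.10) and CDH9 (0.93) in HCT8, and PCDH18 (1.09 ± 0.28) in SW620. MYC fell in HCT116 (-0.97), HCT8 (-1.21) and SW620 (-0.47). All 13 mitochondrial genes were lower in IP in every line (medians -2.64, -2.44, -2.87 and -3.42; adjusted p = 0.031, 0.032, 0.030 and 0.041 with an estimated correlation). G2/M genes were lower in DLD1, HCT116 and HCT8 (adjusted p = 0.031, 0.036 and 0.041 with an estimated correlation), as were heat shock genes (adjusted p = 0.031, 0.024 and 0.029 with an estimated correlation). DESeq2 called 278, 646, 401 and 153 genes (166, 313, 161 and 34 up), and leaving out any 1 of the 4 libraries of a line gave 583 to 1042, 1292 to 2238, 1098 to 1674 and 287 to 335. Library-size scaling gave 290, 850, 486 and 149 up and 2845, 4841, 4865 and 794 down, so the balance of rises and falls depended on the scaling, and it moved the median of all genes by -0.18, -0.19, -0.21 and -0.07 across the 4 lines.

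Repeats called in IP against input numbered 897, 964, 970 and 690 up and 122, 315, 248 and 426 down in DLD1, HCT116, HCT8 and SW620. The excess of rises depended on the scaling, since library-size scaling gave 486, 634, 545 and 545 up and 515, 781, 749 and 602 down. Counts on olfactory receptor genes were higher in IP as well (948.53 to 1023.56 CPM against 787.47 to 882.17 in input), so the shift was not confined to repeats. Other LTR elements rose in all 4 (medians 0.33, 0.42, 0.36 and 0.28; adjusted p = 0.031, 0.024, 0.029 and 0.046 with an estimated correlation), with medians of 0.15, 0.23, 0.16 and 0.21 under library-size scaling. MER61C and LTR10B2, which are known p53-bound LTRs, rose by 1.24 ± 0.05 and 1.21 ± 0.09 in HCT116. In DLD1, where they were chosen after their values were seen, they rose by 0.53 ± 0.06 and 0.55 ± 0.10. Their values in HCT8 and SW620 are not stated in the text, so no pattern across the lines is drawn from them. HERV-K rose in DLD1, HCT116 and HCT8 (adjusted p = 0.033, 0.024 and 0.037 with an estimated correlation), and Alu in HCT116 and HCT8 (adjusted p = 0.046 and 0.041 with an estimated correlation). AluYa4 was the top repeat, at 1.22 ± 0.08, 1.46 ± 0.07, 1.34 ± 0.07 and 1.18 ± 0.08. Young L1 had 8 of 8 members up in each line, and its call was lost (adjusted p = 0.14, 0.12, 0.10 and 0.22 with an estimated correlation). L1HS, the human-specific L1 family and also chosen afterwards, rose by 0.40 ± 0.02, 0.48 ± 0.02, 0.45 ± 0.02 and 0.29 ± 0.02.

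**Figure D4:**
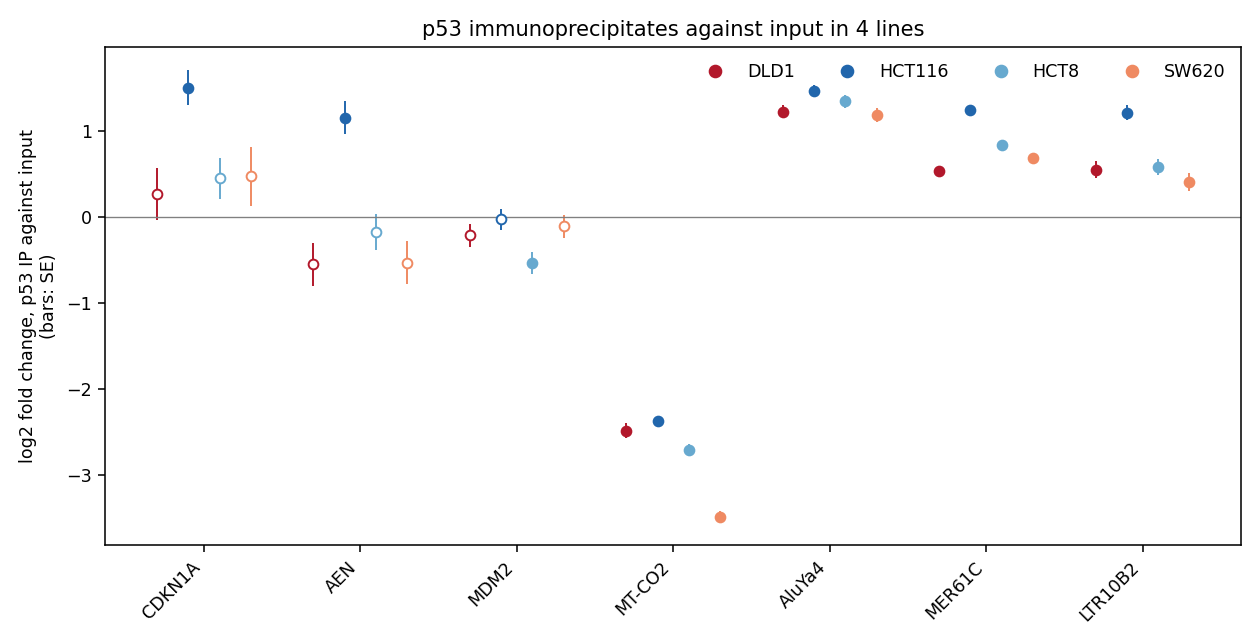
The log2 fold change of p53 IP against input (y axis; bars are standard errors) is plotted for 7 genes and repeats in 4 lines, with 2 libraries per arm; filled points passed an adjusted p of 0.05. MT-CO2 lies below -2.3 in all lines, and CDKN1A and AEN have filled points in HCT116 only.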

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

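The tests of antisense-named genes and of treatment as a source of the xenograft repeat share were chosen only after the result was seen, as were the regroupings for contrasts with 0 calls.

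In the HCT116 xenografts, AZA tumour 2 stood apart from the other 4 of its group in the share of counts on repeats, at 81.31% against 48.13% in the nearest. The same tumour had 0.68% of counts on mitochondrial genes, against 3.12% in the nearest. HCT116 PBS tumour 3 stood apart from the other 3 of its group in mitochondrial share, at 0.82% against 4.03% in the nearest. It also stood apart in its scaling factor, 0.196 against 1.177. These were 4 of 32 group measures tested, where chance gives about 1 in 20.

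The effect of 3TC differed between conditions of sphere state and day for 3 genes in DLD1, 1 in HCT116, 568 in HCT8 and 13 in SW620. The HCT116 gene was MT-ND6, whose ratio to MT-ND5 differed between pools. The effect of 3TC was called different between HCT116 and SW620 tumours for 24 genes, which were 0 without HCT116 PBS tumour 3 and 5 without SW620 3TC tumour 5.

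The established day 1 spheres, which form a pool, differed in strand-related counts. In that pool 656 antisense-named genes stood higher, relative to 13992 protein-coding genes, than in established day 7 spheres, by a median log2 of 0.939, with 48.8% of them over 1; the excess was 0.079 for new day 1 and 0.365 for new day 7. The log2 ratio of MT-ND6, encoded on the light strand, to MT-ND5, on the heavy strand, was higher by a mean of 4.283 in that pool, between 3.48 and 4.6 across the 4 lines. This is consistent with reads of both strands being counted together for MT-ND6 in that pool, a test set before its result was seen. The wider explanation, counting without strand for the whole pool, was not decided. The antisense excess of 0.939 missed the bound of 1, but that bound was set after the result was seen, so missing it does not speak against this explanation. The day conflict in the labels of this pool leaves a difference in culture time open as well. The 3TC contrasts lie within the pool, so MT-ND6 on established day 1 may measure the heavy strand. If the wider explanation holds, other genes with transcripts on the opposite strand are affected too, and this pool enters every line mean.

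The repeat share of xenograft libraries varied widely within treatment groups. CPM summed over olfactory receptor genes rose with the repeat share in HCT116 (n = 22, Spearman's rho 0.801, permutation p = 3e-05; Pearson's r 0.95, permutation p = 1e-05) and SW620 (n = 27, rho 0.929, p = 1e-05; r 0.801, p = 1e-05), where 1e-05 is the smallest p these permutations can give. Both measures are shares of the same library total, so a swing in another fraction moves them together, and the permutations do not allow for this. HCT116 PBS tumour 3, for example, was the lowest HCT116 tumour in both, at 30.07 CPM and 9.1% repeats. Over the 2 lines, the Benjamini-Hochberg values were 3e-05 and 2e-05 for rho and 1e-05 for both r, and without the 2 farthest libraries r was 0.753 and 0.957. This is in line with DNA or other non-transcribed sequence carried into some libraries, since such counts had a median of 845 CPM in ChIP input, against 168.6 in xenografts and 67.9 in spheres of HCT116 and 59.6 and 33.4 in those of SW620, although HCT116 established day 1 spheres reached 122.52 to 175.81 at only 25.55% to 30.04% repeats, so the measure is not specific to DNA. Treatment stayed open: the range within a group was at least 1.613 times the largest difference between group medians in HCT116 and 2.769 in SW620, below the bound of 2 in HCT116, with permutation p = 0.0827 and 0.531.

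Regroupings of the same libraries asked how often chance gives as many calls, with a share under 0.05 as the bound and no correction over contrasts. For the mean effect of 3TC the share was under 0.05 in DLD1 (80 genes, highest other split 99, 2 of 100 splits as large) and HCT116 (16, highest other 1, 1 of 100). It was also in SW620 (30, with the highest other split at over 4 times that count, 2 of 100), and was not in HCT8 (45 up and 86 down, highest other 675, 5 of 100). For the difference between conditions the splits exchanged treatment within each condition. They therefore ask whether 3TC had any effect, and cannot decide whether the effect differs. The counts were 568 in HCT8 (highest other 1280, 4 of 100), 3 in DLD1 (highest other 11, 14 of 100), 1 in HCT116 (highest other 19, 6 of 100) and 13 in SW620 (highest other 448, 12 of 100). The share was under 0.05 for day (7516, highest other 661, 1 of 23) and sphere state (10351, highest other 3099, 1 of 23). For the 3TC difference between tumour lines, where the splits have the same limit, it was not (24, highest other 78, 9 of 34). For the AZA and 3TC with AZA differences the real count was 0, so all splits were certain to be as large (34 of 34 each) and the test decides nothing. Their highest others were 1 and 75. The same holds for the 10 contrasts within a tumour line, with 0 genes (50 of 50 each). The other splits of those contrasts also gave 0 except for SW620 3TC with AZA against 3TC, with 262. Splits that call several times the real count, as in SW620 and the last contrast, point to a structure of the samples other than treatment. In SW620 and that contrast the libraries may not be interchangeable, so a share under 0.05 does not exclude chance. The HCT8 splits cannot show such a structure. Labels were exchanged in each condition separately, so some splits can keep the treatment labels of new day 7, the condition with 2625 calls. Large counts in HCT8 may thus hold the treatment effect itself, and its shares do not decide about chance.

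With 3 libraries against 3, the 10 splits are too few for a share under 0.05. The real count and highest other on new day 1, new day 7, established day 1 and established day 7 were 6 and 1, 92 and 2, 0 and 0, 0 and 0 in DLD1. In HCT116 they were 5 and 4, 71 and 1, 0 and 1, 0 and 0, and in HCT8 1 and 0, 2625 and 1220, 0 and 0, 2 and 0. In SW620 they were 4 and 0, 16 and 683, 40 and 1266 for the first 3 conditions, and splits as large numbered 1, 2 and 4 of 10. The high counts of other SW620 splits point to a structure of the samples, and on established day 1 the replicate letters are part of it: same-letter residuals correlated at 0.176 to 0.743, a replicate block gave 240, and leaving out replicate A, B or C gave 0, 0 and 401. The splits ignore these letters, and splits that keep them would be fewer still. In the other lines 1 of 10 splits was as large where genes were called. Where none were called it was 10 of 10, which a count of 0 makes certain.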

How the results depend on the processing

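The fits without libraries of low scaling factor, without HCT8 new day 7 DMSO replicate B, over 3 conditions and with sample weights were chosen only after the result was seen, as were the list tests in the contrasts of day and sphere state. Of the counts compared, DESeq2's size factors in edgeR kept all 39 within 1.5 times, DESeq2 kept 16, moved 22 and gave calls in 5 that had none, no filter kept 20, moved 14 and gave calls in 9, and a replicate block kept 14, moved 14 and gave calls in 3. Leaving out single libraries kept 182 counts, moved 21, gave calls in 4 and ended 1. Most of the kept counts were xenograft contrasts with 0 calls that stayed at 0, and every ChIP count moved. Over the named genes and lists, 1287 values kept their direction and side of the threshold, 343 fell short of it, 6 passed it and 17 turned sign. Planted changes were recovered less often in the xenograft and single-condition designs than in the line means, which had more libraries, and depth, spread and library number were not separated. Except where fewer samples or genes tested are the change itself, the cause was not tested.

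DESeq2 called 190 genes for the DLD1 mean, 34 for its difference between conditions, 43 on new day 1 and 245 on new day 7. In HCT116 it called 100, 21, 25 and 246 in that order. In HCT8 it called 266 and 1172, then 2 on new day 1, 1 on established day 1 and 9 on established day 7. In SW620 it called 103 and 74, then 56, 54, 104 and 1 over the 4 conditions. For HCT116 tumours it called 76 with 3TC and 1 with 3TC and AZA, for the difference between tumour lines 50 and 2, and for ChIP 278 in DLD1, 646 in HCT116, 401 in HCT8 and 153 in SW620. MDM2 by sphere state turned to -0.086.

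Without a filter, DLD1 gave 23 for the difference between conditions and 12, 282, 1 and 1 over the 4 conditions. HCT116 gave 52 for the mean, 40 for the difference, and 23, 136 and 7 on new day 1, new day 7 and established day 1. HCT8 gave 13, 18 and 7 on new day 1, established day 1 and established day 7, and SW620 gave 82 and 77, then 23, 47, 1.2e+02 (56 up, 60 down) and 7. HCT116 tumours gave 100 with 3TC, 70 with AZA, 43 with both and 3 for both against 3TC.

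A replicate block gave 25 for the DLD1 mean, 3 on new day 1 and 54 on new day 7. It gave 4 for the HCT116 mean, then 3, 45 and 1 on new day 1, new day 7 and established day 1, and in HCT8 3, 1 and 5 on new day 1, established day 1 and established day 7. In SW620 it gave 89 and 102, then 44, 66, 240 and 10, and by day 4240. With DESeq2's size factors MDM2 by sphere state was -0.082.

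Without libraries of low scaling factor, DLD1 gave 152 for the mean, 22 for the difference and 239 on new day 7, and the 3TC difference between tumour lines gave 0. There MDM2 by sphere state was -0.069 and CDKN1A in HCT116 tumours with 3TC -0.032. Without HCT8 new day 7 DMSO replicate B, the HCT8 difference was 281 and new day 7 was 1430. Over 3 conditions the mean was 418 in HCT8 and 18 in SW620. With sample weights, CDKN1A in HCT116 tumours with 3TC was -0.051, HCT116 tumours with both agents against 3TC gave 1, and the 3TC difference between tumour lines gave 0.

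Library-size scaling gave 3135 in DLD1, 5691 in HCT116 and 5351 in HCT8 in ChIP. Of 90 gene list and 64 repeat family calls over the planned contrasts, 31 held with an estimated correlation. Of 204 levels, 1 moved by 1 SD or more with library-size scaling.

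Leaving out each replicate gave, from lowest to highest, 1 to 17 for the DLD1 mean, 0 to 0 for its difference, 0 to 2 on new day 1, 1 to 53 on new day 7, and 0 to 0 on both established days. HCT116 gave 0 to 0, 0 to 0, 0 to 4, 0 to 5, 0 to 0 and 0 to 1 in the same order. HCT8 gave 33 to 57, 98 to 138, 0 to 1, 716 to 1962, 0 to 0 and 0 to 1. SW620 gave 4 to 283, 0 to 617, 2 to 239, 0 to 123, 0 to 401 and 0 to 38. Day gave 5667 to 6131 and sphere state 8253 to 8852. HCT116 tumours with 3TC gave 0 to 19 and the other contrasts within a tumour line 0 to 0, while the differences between tumour lines gave 0 to 58 for 3TC, 0 to 0 for AZA and 0 to 1 for both. ChIP gave 583 to 1042 in DLD1, 1292 to 2238 in HCT116, 1098 to 1674 in HCT8 and 287 to 335 in SW620. In ChIP, and in SW620 established day 7 DMSO spheres without replicate A or C, this left 1 library in an arm. That lone library is assumed to vary like the other groups. The upper ends of the SW620 ranges for the mean, the difference and established day 7 come from such a refit, without replicate C. With a lone DMSO library they cannot show how far the calls depend on single replicates, and no conclusion is drawn from them.

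The sign of single values turned when replicates were left out. CDKN1A ran from -0.277 to 0.155 by day, and MDM2 from -0.074 to 0.074 by sphere state. In HCT116 tumours with AZA, MDM2 ran from -0.029 to 0.419, and with 3TC, CDKN1A ran from -0.031 to 0.344. In SW620 tumours with AZA, CDKN1A ran from -0.568 to 0.119 and MDM2 from -0.02 to 0.168, and with both MDM2 ran from -0.02 to 0.082. In ChIP, MDM2 ran from -0.123 to 0.03 in HCT116 and -0.253 to 0.012 in SW620.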

Other observations

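The list tests by day and sphere state were chosen only after the result was seen, as were the genes named with them and the value for DLD1 without replicate C, while the test of olfactory receptor counts by day was not.

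Single stress and metabolic genes differed between days in DMSO spheres, while no list named here held with an estimated correlation. Neither day nor sphere state can be told apart from the pool. DDIT3, a transcription factor of endoplasmic reticulum stress, rose by 1.25 ± 0.10 from day 1 to day 7, and ASNS, which makes asparagine under amino acid shortage, by 1.28 ± 0.18, both chosen after their values were seen. The integrated stress response list had a median of 0.54 (adjusted p = 0.42 with an estimated correlation), while interferon-stimulated genes had a median of 0.26 (adjusted p = 0.40 with an estimated correlation) and hypoxia genes a median of -0.95 with 12 of 17 down (adjusted p = 0.42 with an estimated correlation). LDHA fell by 1.32 ± 0.09 and PDK1, which diverts pyruvate from mitochondria, fell by 0.95 ± 0.16. WNT and intestinal stem cell genes had a median of -0.42 (adjusted p = 0.38 with an estimated correlation). In established spheres IFI27, an interferon-stimulated gene, rose by 1.71 ± 0.27 over new spheres on day 7, and antigen presentation genes had 11 of 14 up with a median of 0.52 (adjusted p = 0.294 with an estimated correlation).

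Repeat families were called higher on day 7 than on day 1 in new DMSO spheres, over the 4 lines together. Olfactory receptor counts on day 7 against day 1 were tested for carried-over DNA, and the smallest change was -0.286 (HCT116), against 1.77 in DLD1 (0.359 without new day 7 DMSO replicate C), 0.05 in HCT8 and 0.92 in SW620. The test decided nothing, because the repeat share of every day 7 library lay above every day 1 library only in SW620 (39.58% or more against 31.7% or less), a condition set after the result was seen. Carried-over DNA and the pool both stayed open as sources.

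The xenograft library whose title and cell line label name different lines held 2.52 M counts, of which 35.84% lay on repeats and 4.16% on mitochondrial genes.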
